A study of Mus musculus with 12 samples.

How the data were processed

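Gene expression was measured on Affymetrix arrays in liver sinusoidal endothelial cells (LSECs), the fenestrated, highly endocytic endothelium that lines the liver's capillaries. Per the labels, the cells were isolated from mouse livers with CD146 beads. The 12 arrays form 4 genotypes with 3 arrays each, and each array holds RNA pooled from 3 mice aged 3 to 4 months. The genotypes were wild type (WT), loss of Stab1 (Stab1KO), loss of Stab2 (Stab2KO) and loss of both (DKO). Per the labels, each pool is a separate biological replicate, and the strain of all samples is C57BL/6J. The labels do not say whether WT and knockout mice were littermates, so a difference of colony or substrain is not separated from genotype in the comparisons against WT.

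The deposited values are log2 expression values, 1 per gene identifier and array, and the submitters' processing notes name RMA, a method that corrects background, normalizes by quantiles and summarizes probes. The genome build and the version of RMA are not given in the sources used here. The table held 24973 rows with values between 2.94 and 13.9. The sorted values of 11 arrays were identical, and those of DKO replicate 1 differed from them by at most 0.00187 at any rank. No detection calls or scanner intensities were used here, so no gene is called absent, and values near the lower end hold an unknown share of background. For arrays, the number of pools limits the precision.

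Row identifiers were paired with gene symbols through the platform annotation. Of the rows, 24015 had 1 symbol, 0 had several, and 958 were not listed there and are unnamed here. Where rows shared a symbol, the row with the highest mean over the 12 arrays was kept, which left out 4 rows and gave 24011 genes tested. Of these, 23918 had the same symbol and a position in the RefSeq annotation of GRCm38.p6, which was used only to find which genes lie near each other.

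The test was limma 3.58.1 in R 4.3.3: 1 linear model with 4 group means over the 12 arrays, moderated tests of both signs without trend or robust options, and Benjamini-Hochberg adjustment over the 24011 genes within each of 7 contrasts. A gene was called at an adjusted p under 0.05. The contrasts were each knockout against WT, DKO against each single knockout, the single knockouts against each other, and the departure from additivity, defined as the Stab1 effect without Stab2 minus the Stab1 effect with Stab2. A moderated F-test covered the 3 contrasts against WT. Fold changes are log2 differences with the moderated standard error (SE). The adjusted p-values in the text are limma's.

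The 50 gene lists of cell types and functions, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 772 different list genes, 716 were measured. Lists were tested with camera at a preset correlation between genes of 0.01, and adjusted within each contrast over the 49 lists with at least 3 measured members. They were tested again with the correlation estimated per list, and with fry, which tests whether the genes of a list move on balance one way. The rule named Stab1 and Stab2, then the 10 largest rises and 10 largest falls of each comparison against WT, or 5 of each in the other contrasts, among called genes whose 3 arrays of 1 genotype all lay above or all below the 3 of the other. It also named up to 4 called members of each list, or, where none was called, up to 2 members with the largest change, as values only. Gene models with placeholder symbols and small RNAs were counted but not named.

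On simulated arrays for Stab1KO against WT, with the real genes' means and spreads, the model recovered 30% of genes changed by 0.5 log2, 92% of those changed by 1 and 98% of those changed by 2, with 12 false calls among 172 calls over 24011 genes. For the departure from additivity, 10% of genes changed by 0.5 and 62% of those changed by 1 were recovered, with 4 false calls among 137. A list lowered by 1 log2 was called by camera, and 0 of the other lists were. The simulated genes varied independently, so this does not show how often camera calls a list falsely when its genes correlate.

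The labels number the replicates 1 to 3 in each genotype. Alternatives were a block for that number, a filter on low signal that kept genes above the 40th percentile of the gene means, eBayes with trend and robust options, array weights, median centring with a further quantile normalization, every row tested, a minimum log2 fold change of 1, only the 6 arrays compared, and each array left out in turn. For the correlations of effects, genes within 20 Mb of Stab1 or Stab2 were also left out. The mean of the stellate list as a covariate, and the estimated correlation without DKO replicate 3, were added after the data were seen. Whether the targeted gene counts in the window tests was not fixed beforehand, and both versions are given.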

Results

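The data were 12 expression profiles of bead-isolated LSECs from 4 mouse genotypes, with 3 pools of 3 mice each. Stab1 and Stab2 encode stabilin-1 and stabilin-2, the class H scavenger receptors of this endothelium. The comparisons ask how the expression profile of these cells differs when either receptor or both are missing. The arrays shared a median of 5.11 log2. Among 11 arrays every pairwise correlation across genes was at least 0.987, while DKO replicate 3 correlated with the others at 0.956 to 0.968. In that array the mean of the 14 measured neutrophil genes was 5.04 log2 above the mean of the 12 arrays, against -0.07 in DKO replicate 1 and 0.36 in DKO replicate 2.

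The targeted genes followed the labels in every array. Stab1 measured 12.54 ± 0.08 log2 in WT and 12.53 ± 0.06 in Stab2KO, against 5.31 ± 0.14 in Stab1KO and 5.23 ± 0.23 in DKO (mean ± SD, n = 3 pools each). Stab2 measured 13.05 ± 0.05 in WT and 13.004 ± 0.02 in Stab1KO, against 6.81 ± 0.57 in Stab2KO and 6.65 ± 1.09 in DKO. Stab1 fell by 7.24 in Stab1KO and by 7.31 in DKO, and Stab2 fell by 6.24 and by 6.40 on the log2 scale in its own knockouts. The exact permutation p of each of these 4 comparisons was 0.1, the smallest that 3 against 3 arrays allow. Neither receptor changed when the other was lost: Stab2 differed by -0.04 ± 0.44 (SE) in Stab1KO, and Stab1 by -0.01 ± 0.12 in Stab2KO. The model shares the spread of a gene over all groups. The large SE for Stab2 thus reflects its SDs of 0.57 and 1.09 where it was lost, not those of 0.05 and 0.02 in the groups compared. The gene next to each target rose with its loss. Nt5dc2, the neighbour of Stab1, rose by 4.55 ± 0.14 in Stab1KO and 4.04 ± 0.14 in DKO (adjusted p = 4.7e-08 and 1.1e-07). Nt5dc3, the neighbour of Stab2, rose by 2.72 ± 0.19 in Stab2KO and 2.57 ± 0.19 in DKO (adjusted p = 0.00023 and 0.00011).

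**Figure D1:**
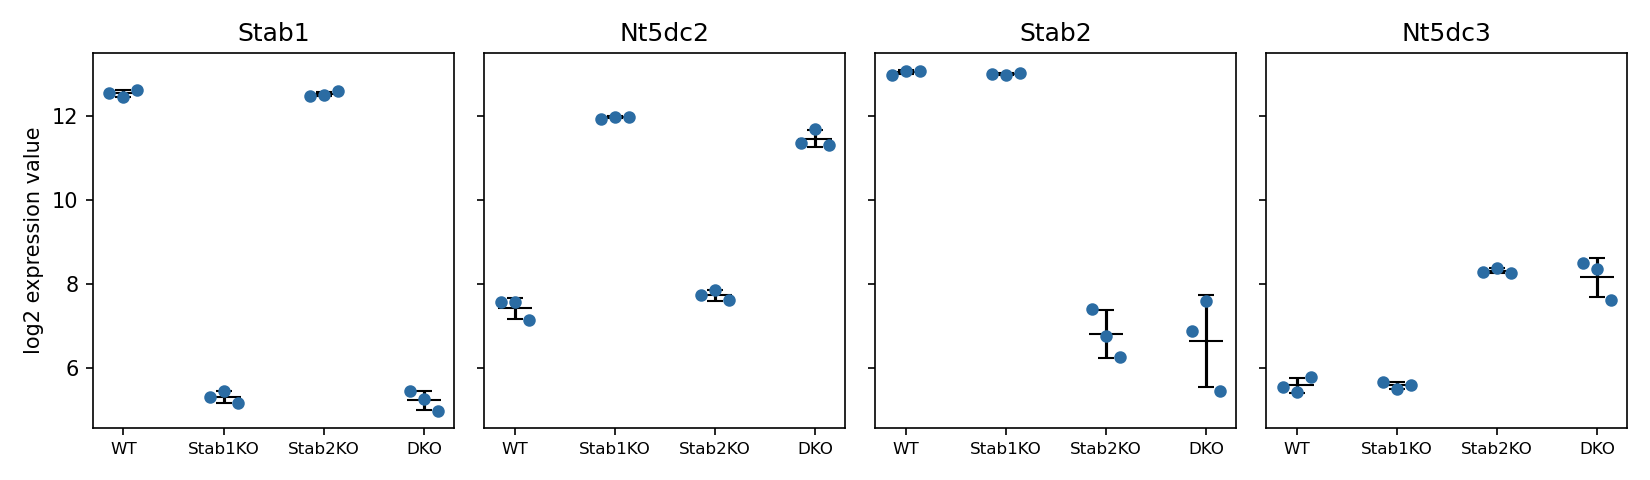
Log2 expression of Stab1, Nt5dc2, Stab2 and Nt5dc3 in the 4 genotypes, with 1 point per array and the mean ± SD of 3 arrays in black. Stab1 falls and Nt5dc2 rises in Stab1KO and DKO, and Stab2 falls and Nt5dc3 rises in Stab2KO and DKO.

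Without Stab1, many of the genes that fell most were genes of hepatic stellate cells, the vitamin A-storing pericytes of the sinusoid. Among them were the bone morphogenetic protein gene Bmp5 (-3.32 ± 0.23 log2) and Lrat (-3.01 ± 0.26), which encodes the enzyme that esterifies retinol for storage. Of 19 measured stellate genes 10 fell and 0 rose, or 16 and 0 adjusted over the list alone, with a median log2 fold change of -1.39 (camera adjusted p = 5.1e-58, and adjusted p = 0.0033 with an estimated correlation). Reln (-2.62), the proteoglycan gene Lum (-2.61) and Colec11 (-2.60) of the same list fell. Falls outside the list, which does not hold every stellate gene, were in the collectin gene Colec10 (-3.12 ± 0.33), Tlcd4 (-2.73), Bmp10 (-2.52) and the matrix protein gene Postn (-2.47). The chemokine gene Cxcl12 (-2.42 ± 0.19), Gdf2 (-2.20 ± 0.23), which encodes BMP9, and the protease gene Adamts13 (-0.70 ± 0.11) fell as well. The 7 rises were Nt5dc2, Entpd1 (1.32 ± 0.20), Nnt (1.13 ± 0.15), Morn4 (1.10 ± 0.13), Ptgfrn (0.74 ± 0.10), C2 (0.67 ± 0.09) and St6gal1 (0.35 ± 0.06).

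In all, 74 genes were called in Stab1KO against WT, 67 of them lower. The list of stabilin ligands was lower, with 2 of 9 members called, Postn and Reln, or 5 adjusted over the list alone (camera adjusted p = 2.1e-09, and adjusted p = 0.015 with an estimated correlation, which was 0.061 without DKO replicate 3). So was the TGF-beta and matrix list, with Postn and Col6a1 called among 28, or 7 adjusted over the list alone (adjusted p = 0.0006, and 0.049 with an estimated correlation, which was 0.10 without DKO replicate 3). Its median of -0.02 lay near 0 beside a mean of -0.22. These lists are not independent of the stellate list: each shares 3 members with it, among them Col1a1 and Col3a1, and their called members Postn, Reln and Col6a1 fell in all 3 knockouts with the stellate genes. MHC class I and large-vessel endothelial genes were higher at the preset correlation, with medians of 0.17 and 0.25 and no member called (adjusted p = 2.1e-05 and 3.5e-05, and adjusted p = 0.40 for each with an estimated correlation). The mean of the large-vessel list was 0.32, and 0.19 without WT replicate 2. Of the 26 LSEC identity genes and the 28 scavenger receptor genes, 0 were called over all genes or adjusted over the list alone. Their median log2 fold changes were -0.03 and 0.00. The count was 47 without Stab1KO replicate 2 and 46 without Stab1KO replicate 3. Of 21 named genes called here, 5 (Adamts13, C2, Col6a1, Entpd1 and St6gal1) lost the call when some single array was left out.

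Without Stab2, the phospholipase gene Pla2g7 rose by 3.54 ± 0.55 log2, the meiotic recombination gene Msh5 by 2.63 ± 0.28 and the chloride channel gene Clic5 by 1.46 ± 0.17. Smaller rises were in Sdc1 (0.99 ± 0.12), Tnni3 (0.97 ± 0.13), Sncg (1.09 ± 0.18) and Pdlim3 (1.19 ± 0.20). Ass1 (-2.54 ± 0.33), which encodes a urea cycle enzyme, and Lrmda (-2.15 ± 0.16) fell. The stellate genes Bmp5 (-2.52 ± 0.23), Lum (-2.14 ± 0.13) and Lrat (-2.05 ± 0.26) fell here too, as did Colec10 (-2.43 ± 0.33), Postn (-2.07 ± 0.28), Hhip (-2.06 ± 0.21) and Tlcd4 (-1.95 ± 0.26). Of the 19 stellate genes 9 fell and 0 rose, or 16 and 0 adjusted over the list alone, with a median of -0.99 (camera adjusted p = 6.5e-30, and adjusted p = 0.032 with an estimated correlation, which was 0.099 without DKO replicate 3). The MHC class I genes H2-T23 (-1.33 ± 0.16) and H2-Q7 (-1.05 ± 0.17) fell, and the transcribed pseudogenes H2-T10 (1.42 ± 0.22) and Tdg-ps2 (2.03 ± 0.32) rose. These genes have near-identical copies, so their values are uncertain. Stab2 was also missing in DKO, yet some genes of this paragraph lay nearer WT there. In WT, Stab2KO and DKO, Msh5 measured 6.39, 9.02 and 6.22, and Lrmda 8.46, 6.31 and 8.15. H2-T23 measured 10.4, 9.07 and 10.5, and Clic5 5.63, 7.09 and 6.25. Others, such as Ass1 (7.97, 5.44 and 5.37) and Tdg-ps2 (5.15, 7.18 and 7.04), stayed changed in DKO. Msh5, Clic5, H2-Q7 and H2-T23 lie on chromosome 17. For them a segment carried by the Stab2KO line is not separated from loss of Stab2.

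In all, 71 genes were called in Stab2KO against WT, 20 higher and 51 lower. Kupffer cell genes, those of the liver's resident macrophages, had a median of -1.12, all 16 were below WT, and 0 were called over all genes or adjusted over the list alone (camera adjusted p = 8.5e-11, but adjusted p = 0.64 with an estimated correlation). The mean of the list was -1.10, and -0.67 without WT replicate 2, and WT replicate 1 (-0.69) lay within the range of the Stab2KO arrays (-0.99 to -0.61). Vsig4 and C1qc differed by -1.83 ± 0.59 and -1.57 ± 0.46 without passing the test. All 15 natural killer cell genes were above WT with a median of 0.62 and 0 called (adjusted p = 5.3e-06, and 0.73 with an estimated correlation). Their mean of 0.64 was 0.41 without WT replicate 1 and 0.96 without WT replicate 3. All 21 cell cycle genes were above WT with a median of 0.28 and 0 called (adjusted p = 0.00018, and 0.73 with an estimated correlation). Their mean of 0.31 was 0.21 without WT replicate 1 and 0.20 without Stab2KO replicate 1, and neither passed (adjusted p = 0.084 and 0.075). Stabilin ligands were lower, with Postn and Reln called of 9, or 5 adjusted over the list alone (adjusted p = 6.9e-06, and 0.072 with an estimated correlation). Scavenger and endocytic receptors had a median of -0.09 and 0 of 28 called (adjusted p = 0.0043, and 0.73 with an estimated correlation). Its members with the largest differences, Cd163 and Lrp1, measured -1.50 ± 0.48 and -1.30 ± 0.32. The count was 37 without WT replicate 2, 42 without WT replicate 3, 47 without Stab2KO replicate 1 and 33 without Stab2KO replicate 2. Only 29 genes were called with the 6 compared arrays alone. Of 29 named genes called, 14 lost the call when some single array was left out, among them Pla2g7, H2-T10, Sncg, Pdlim3 and Reln.

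Without both receptors, Btnl9, a butyrophilin-like gene of endothelium, fell by 6.78 ± 0.21 log2, from 11.67 ± 0.14 (SD, n = 3) in WT to 4.90 ± 0.38 in DKO. The olfactory receptor gene Olfr1396 fell by 4.69 ± 0.32, to 3.61. Both DKO values lay below the array median of 5.11 and were not shown to exceed background, so the falls in expression may be larger than the measured differences. The stellate genes Bmp5 (-3.70 ± 0.23), Lrat (-3.68 ± 0.26), Colec11 (-3.14 ± 0.17) and Reln (-2.81 ± 0.32) fell, as did Colec10 (-3.79 ± 0.33) and Tlcd4 (-3.11 ± 0.26). Of 19 stellate genes 12 fell and 0 rose, or 16 fell and 1 rose adjusted over the list alone, with a median of -1.07 (camera adjusted p = 4.9e-19, but adjusted p = 0.13 with an estimated correlation). Acta2 of this list went the other way, at 6.97 in WT, 8.11 in Stab2KO and 8.98 in DKO. Tagln measured 6.24 in WT and 6.58 in DKO. Beside Nt5dc2 and Nt5dc3, the largest rises were in the immunoglobulin gene Ighg2c (2.51 ± 0.37), Nr4a3 (2.37 ± 0.46), Retreg1 (2.15 ± 0.43), Ankrd1 (2.15 ± 0.35), Nr4a1 (2.13 ± 0.42), Nabp1 (2.01 ± 0.30), Egr2 (2.00 ± 0.35) and the pseudogene Olfr1372-ps1 (2.21 ± 0.37). Without DKO replicate 3, Nr4a3 and Nr4a1 no longer passed (adjusted p = 0.060 and 0.062). Retreg1, Ankrd1, Egr2 and Olfr1372-ps1 lost the call without some other array.

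Immediate early genes, which respond within minutes to stimuli and to cell dissociation, were higher in DKO. Of 22 members 4 rose and 0 fell, or 13 and 0 adjusted over the list alone, with a median of 0.60. Examples were Egr2, Ier2 (1.11 ± 0.20) and Ier3 (1.05 ± 0.20). Of 24 interferon-stimulated genes 3 rose, or 12 adjusted over the list alone, with a median of 0.53: Oasl1 (1.33 ± 0.25), Oasl2 (0.66 ± 0.11) and Cmpk2 (0.52 ± 0.11). Large-vessel endothelial genes were higher, with Selp (1.57 ± 0.27), Gja5 (0.63 ± 0.12) and Fbln2 (1.40 ± 0.27) called of 17, or 11 rises and 1 fall adjusted over the list alone. Of 7 cholangiocyte genes, those of bile duct epithelium, 4 rose, or 6 adjusted over the list alone: Muc1 (1.86 ± 0.29), Sox9 (1.63 ± 0.32), Epcam (1.27 ± 0.25) and Krt19 (1.23 ± 0.25). The camera adjusted p-values of these 4 lists were 1.5e-11, 2.7e-10, 3.0e-08 and 2.7e-08. With an estimated correlation the adjusted p-values were 0.33, 0.29, 0.14 and 0.23. Without DKO replicate 3, 1 cholangiocyte gene was called instead of 4. Of the genes named in this paragraph, Muc1 alone kept the call without each array in turn. The immediate early list was also called at the preset correlation in Stab1KO against WT, but lower there. Its mean relative to the 12 arrays was -0.35 in Stab1KO, -0.14 in WT, -0.09 in Stab2KO and 0.58 in DKO. The call in Stab1KO was lost without WT replicate 3 or Stab1KO replicate 2.

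LSEC identity genes were lower in DKO, with a median of -0.23 and 23 of 26 members below WT. Fam167b (-0.63 ± 0.09) and Plxnc1 (-0.66 ± 0.13) fell, or 11 adjusted over the list alone (camera adjusted p = 1.8e-06, and adjusted p = 0.43 with an estimated correlation). Without DKO replicate 3 the median was -0.13. The endocytosis machinery and lysosome lists were lower, with medians of -0.23 and -0.17 (adjusted p = 2.9e-05 and 0.00089, and adjusted p = 0.29 and 0.33 with an estimated correlation). In them the adaptor gene Ap2s1 fell by 0.53 ± 0.09 and Hexa, a lysosomal hexosaminidase subunit gene, by 0.83 ± 0.09, while Gla, another lysosomal enzyme gene, rose by 0.80 ± 0.17. Counts adjusted over the list alone were 1 lower for endocytosis machinery, and 6 lower and 2 higher for lysosome. The scavenger receptor gene Colec12 fell by 0.70 ± 0.09, and the other 27 genes of its list were not called. The angiogenic factors Vegfa and Vegfc rose by 1.47 ± 0.23 and 1.36 ± 0.25, and Cd34, an endothelial sialomucin gene, by 0.93 ± 0.13. Plxnc1, Ap2s1, Gla, Vegfa and Vegfc lost the call without some single array.

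In all, 432 genes were called in DKO against WT, 181 higher and 251 lower. Without DKO replicate 3, 424 genes were called, 249 higher and 175 lower, and 267 of the 432 were among them. All 14 neutrophil genes were above WT with 0 called, and their median was 2.81 with that array and 1.05 without it (camera adjusted p = 3.8e-08 and 3.8e-07, and adjusted p = 0.39 with an estimated correlation). The count was 261 without DKO replicate 1, 233, 125 and 133 without WT replicates 1, 2 and 3, and 276 without Stab2KO replicate 2. It was 97 with the 6 compared arrays alone. Of 67 named genes called, 40 lost the call when some single array was left out. Bmp5, Lrat, Btnl9, Colec10 and Colec11 did not.

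**Figure D2:**
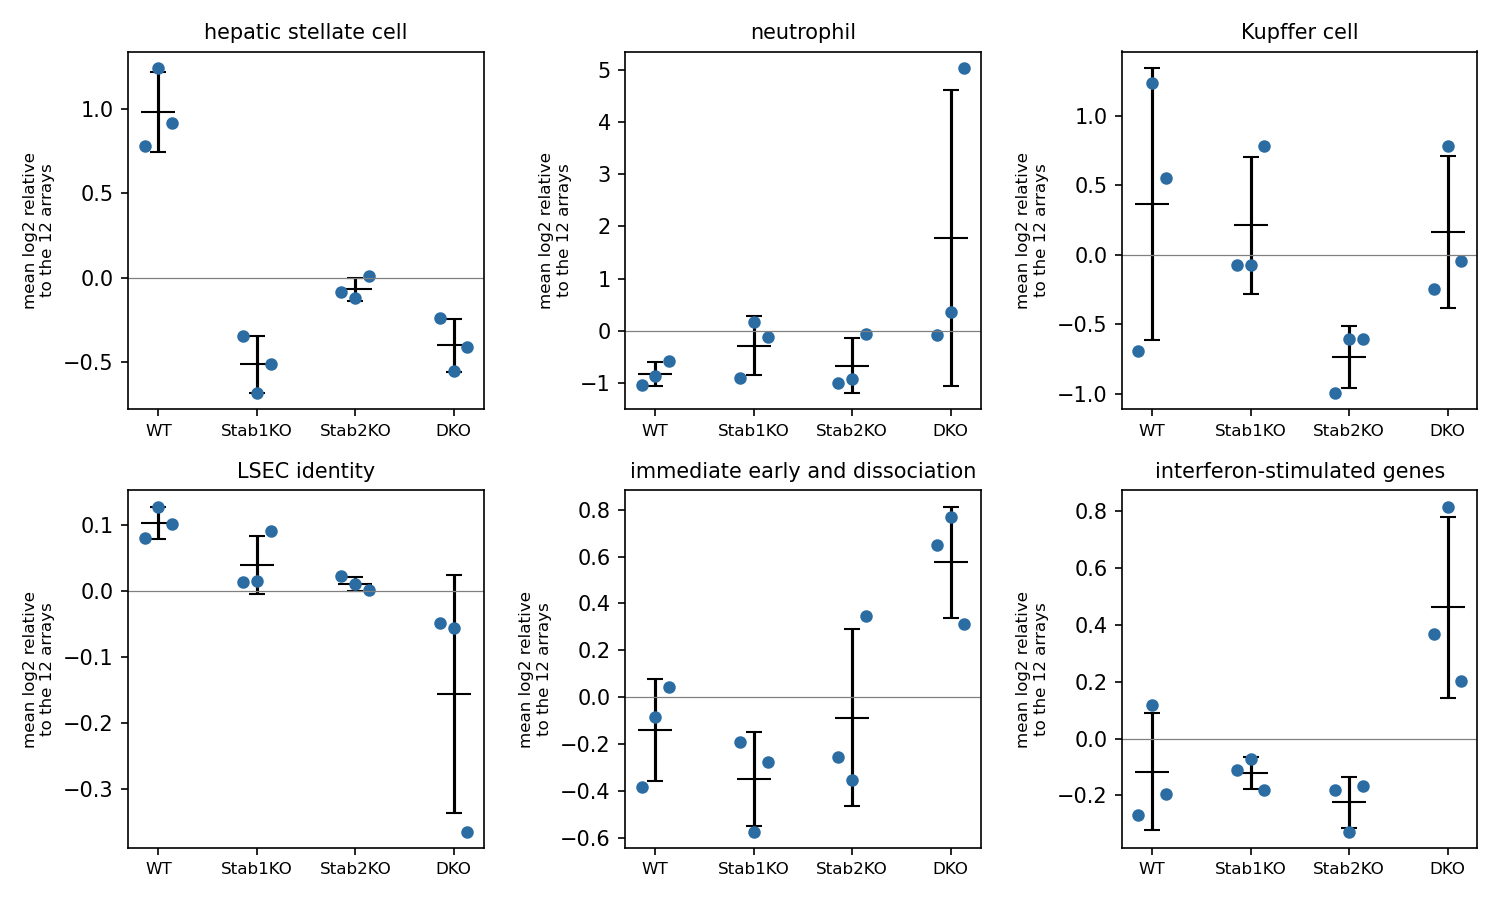
Mean log2 value of 6 gene lists in each array, relative to the mean of the 12 arrays, with 1 point per array and the mean ± SD of 3 arrays in black. The stellate list lies at 0.78 or above in WT and at or below 0.01 in the other arrays, and the neutrophil list lies at 5.04 in 1 DKO array.

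The falls were shared between the knockouts. In Stab1KO and Stab2KO 37 genes fell in both, where independent lists would share 0.14. Stab1KO and DKO shared 58 falls, where 0.70 would be shared, and Stab2KO and DKO shared 41, where 0.53 would be. Genes that fell in all 3 numbered 36, of which 9 are on the stellate list, and 0 genes rose in all 3. All 36 were also called without DKO replicate 3. Whether WT and knockout mice were littermates is not given in the labels, so these falls are differences from this WT group. Members outside the stellate list were Cxcl12 (-2.42, -1.70 and -2.52 in Stab1KO, Stab2KO and DKO), Gdf2 (-2.20, -1.58 and -2.50), Colec10 and Postn. Being outside that short list does not show that a gene is expressed in LSECs. The genes outside it followed the list's mean within groups with a median correlation of 0.47. The 3 comparisons share the WT arrays, and 3 arrays cannot be split into sets of at least 2, so the overlaps were compared with simulated unchanged groups that share their controls. These shared 0, 0.01 and 0.02 called genes on average for the 3 pairs. They gave correlations of fold changes of 0.50 for each pair, against observed values of 0.47, 0.39 and 0.32 for the same pairs. The covariances were 0.0192, 0.0260 and 0.0256, against simulated values of 0.0170, 0.0169 and 0.0169. Each gene was simulated independently and unchanged, so overlaps near 0 were fixed in advance. The simulation does not cover a WT group in which correlated genes, such as the stellate genes, lie higher together.

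Comparisons that share no array gave low correlations across genes. The Stab1 effect with Stab2 present and with Stab2 missing correlated at 0.10 (Spearman 0.01), and the Stab2 effect with and without Stab1 at 0.09 (Spearman 0.04). Genes are not independent replicates, so no p is given. Called with the same sign in both backgrounds were 17 genes for Stab1 loss, where 1.27 would be shared by chance, and 9 for Stab2 loss, where 0.34 would be. Each count includes the deleted gene itself, whose fall in both is fixed by the design. The 17 include Nt5dc2, Morn4, Mfsd13a, Bmp5 and Lrat, and the 9 include Nt5dc3, Ass1 and Cep83os. Nt5dc2 and Nt5dc3 are the neighbours of the targets, and Cep83os lies within 20 Mb of Stab2. Morn4 and Mfsd13a both lie on chromosome 19. A chromosome segment carried along with a targeted gene could recur in DKO. These shared calls therefore do not separate such a segment from loss of the receptor.

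DKO differed from Stab1KO in 227 genes, 131 higher and 96 lower. Ankrd1 (2.81 ± 0.35), Nr4a3 (2.48 ± 0.46), Nr4a1 (2.34 ± 0.42) and Egr2 (2.30 ± 0.35) were higher in DKO, and Btnl9 (-6.56 ± 0.21), Olfr1396 (-4.61 ± 0.32), Ass1 (-2.79 ± 0.33) and Cep83os (-1.62 ± 0.21) were lower. All 4 of these rises, and Cep83os, lost the call without some single array: Nr4a3 with any 1 of 8 arrays left out, DKO replicate 3 among them (adjusted p = 0.055), Nr4a1 with any 1 of 6 left out, Egr2 without Stab1KO replicate 2 or 3, and Ankrd1 and Cep83os without Stab1KO replicate 2. Without DKO replicate 3 the count was 357, 270 higher and 87 lower. It was 22 and 28 without Stab1KO replicates 2 and 3, 115 without DKO replicate 1, 112 without WT replicate 3 and 123 without either Stab2KO replicate 1 or 2. Only 18 genes were called with the 6 compared arrays alone.

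DKO differed from Stab2KO in 822 genes, 313 higher and 509 lower. H2-T22 (4.25 ± 0.71), a class I gene with near-identical copies, Ifi208 (2.53 ± 0.59), Cfap69 (2.42 ± 0.25) and Nr4a3 (2.26 ± 0.46) were higher in DKO. Btnl9 (-5.96 ± 0.21), Olfr1396 (-3.64 ± 0.32), Msh5 (-2.79 ± 0.28) and Pla2g7 (-2.56 ± 0.55) were lower. For H2-T22, Ifi208 and Msh5, Stab2KO was the group farther from WT. H2-T22 measured 9.65 in WT, 9.93 in DKO and 5.69 ± 1.97 (SD, n = 3) in Stab2KO. Ifi208 measured 7.34, 6.77 and 4.23 ± 1.52 in the same order, and Msh5 6.39, 6.22 and 9.02. Pla2g7, raised in Stab2KO, measured 7.46 in WT and 8.44 ± 1.49 in DKO. Cfap69 (5.89 in WT, 7.77 in DKO), Nr4a3, Btnl9 and Olfr1396 differed from WT in DKO. Ifi208 lost the call with any 1 of 11 arrays left out, Pla2g7 with any 1 of 9 left out, and Nr4a3 with any 1 of 4 left out, DKO replicate 3 among them (adjusted p = 0.053). Without DKO replicate 3 the count was 821, 470 higher and 351 lower, and 480 genes were common to both. The count was 45 and 81 without Stab2KO replicates 2 and 1, 366 without DKO replicate 1, and 513, 433 and 423 without WT replicates 1, 2 and 3. Only 4 genes were called with the 6 compared arrays alone.

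Stab1KO and Stab2KO differed in 26 genes, 14 higher and 12 lower in Stab1KO. Apart from the targets and their neighbours, Ass1 (2.72 ± 0.33), Lrmda (2.10 ± 0.16) and H2-T23 (1.55 ± 0.16) were higher in Stab1KO, and Msh5 (-2.84 ± 0.28), Tdg-ps2 (-2.24 ± 0.32) and Mfsd13a (-1.29 ± 0.14) were lower. The count was 43 without DKO replicate 3, 13 without Stab1KO replicate 1, 17 without Stab2KO replicate 1 and 12 without Stab2KO replicate 2. Ass1 lost the call with any 1 of 3 arrays left out and Tdg-ps2 with any 1 of 9 left out.

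The effect of losing Stab1 departed from additivity in 12 genes, 8 with positive and 4 with negative departures. Btnl9 had the largest (-5.74 ± 0.30, adjusted p = 2.7e-05): its Stab1 effect was -0.22 with Stab2 present and -5.96 without it. Olfr1396 (-3.55 ± 0.45), Nnt (-1.47 ± 0.21), a gene deleted in part in the C57BL/6J substrain, and Sult1a1 (-0.89 ± 0.12) departed the same way. Kank1 (2.84 ± 0.21), Sod3 (2.45 ± 0.29), Agtr1a (1.90 ± 0.24) and Lrmda (1.89 ± 0.23) departed upward. For Lum (2.20 ± 0.19) additivity predicts 1.58 log2 in DKO, below the smallest value of the table (2.945), so an upward departure was fixed by the floor and shows nothing about additivity. For the other 11 genes the prediction was 3.66 or above. For Agtr1a (4.03), Elf3 (4.23), Lsmem1 (4.50) and an unnamed gene model (3.66) it lay below the array median of 5.11, where values were not shown to exceed background. Agtr1a measured 5.67, 5.86 and 5.93 in Stab1KO, Stab2KO and DKO, so its upward departure may come from the floor too. Sod3 and Agtr1a were among the genes lower in all 3 knockouts. Btnl9 and Kank1 kept the call without each of the 12 arrays in turn, and the other named genes except Lum lost it without some array. The test for called genes close together on chromosomes, given below, did not cover contrasts with DKO. For Btnl9 and Olfr1396 a segment carried by the DKO line is therefore not separated from the loss of both receptors. The count was 112 without DKO replicate 3, 4 without DKO replicate 1, 19, 4 and 5 without WT replicates 1, 2 and 3, 38, 5 and 3 without Stab1KO replicates 1, 2 and 3, and 3 and 56 without Stab2KO replicates 2 and 3. The F-test over the 4 genotypes called 390 genes. That count was 173 and 229 without DKO replicates 1 and 2, 207 and 164 without WT replicates 2 and 3, 232 without Stab1KO replicate 3, and 189 and 191 without Stab2KO replicates 1 and 2.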

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

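The tests on stellate genes, on neutrophil genes and on chromosome clusters, the splits of the effect correlations, and the leaving out of the targeted gene from the window tests were chosen after the results were seen. For 12 genes the effect of losing Stab1 differed with and without Stab2 in a test of the difference itself. The departures were -5.74 for Btnl9, -3.55 for Olfr1396, -1.47 for Nnt, -0.89 for Sult1a1, 2.84 for Kank1, 2.45 for Sod3, 2.20 for Lum, 1.90 for Agtr1a, 1.89 for Lrmda, 1.52 for Elf3, 1.35 for Lsmem1 and 1.32 for an unnamed gene model. Of 100 splits of the 12 arrays, the real one included, 3 called 12 genes or more, and the highest other split called 64. The splits mixed all genotypes, so they stand for no effect of genotype at all rather than for additive effects. They therefore cannot exclude chance for these departures. The split with 64 may reflect a structure of the arrays other than genotype, or the instability of a count that ran from 3 to 112 over single arrays left out, and what it shares was not tested. Additivity predicts a value below the floor for Lum, so its departure is void. For Agtr1a it predicts 4.03, below the array median of 5.11 and not shown to exceed background, so a part played by the floor is not excluded.

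For the stellate cell genes, lower in all 3 knockout groups, a smaller endothelial share in the WT isolates is argued against for Stab1KO, the group named in the test: the 13 other non-endothelial lists had a median of 0.00407 over their median log2 fold changes, with a range from -0.28 to 0.59, while the stellate list lay at -1.39. The stellate list lay 2.39 SD below the mean of the others in Stab2KO (their median -0.00415), past the 2 SD set for Stab1KO although the Kupffer list was lower too (-1.12). In DKO it lay 1.61 SD below, short of that, where the neutrophil list of replicate 3 widens the SD of 0.85. The others had a median of 0.0262 there and a lowest value of -0.38 (Kupffer), against -1.07 for the stellate list. A smaller endothelial share in WT would lower these lists together, which their median in DKO does not show. With the stellate list short of 2 SD there, the question is not decided for DKO. Genes near background cannot fall much, and signal over background was not measured for these lists. Unequal stellate cell RNA may account for the pattern and stays open, although the CD146 selection is meant to leave stellate cells out; 4 of the 19 list genes are also on other lists. The 27 genes that fell in all 3 groups and are not on the list followed the list's mean within groups with a median correlation of 0.47, above the 0.11 that 95% of random sets stay under but short of the 0.5 set for that test. The highest values on the list in WT were Dcn (12.01), Ecm1 (11.11) and Rgs5 (10.67), which on arrays do not rank abundance between genes, and 3 pools per genotype do not separate a different yield of stellate cells from an effect of genotype on them.

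Neutrophil genes stood out in DKO replicate 3. An effect of genotype equal in the 3 DKO pools is argued against, because the higher of the medians of DKO replicates 1 and 2 against WT was 1.38, against 6.18 in replicate 3. Neutrophil RNA in that pool may be the source: 12 of the 14 measured members were at least 2 log2 above every other array, with Ngp at 13.15, Mmp9 at 12.85 and Ltf at 12.66. Monocyte genes were highest in that array too. The mean of their list, relative to the 12 arrays, was 1.84 there, 0.14 in DKO replicate 2 and -0.06 in DKO replicate 1. The monocyte list passed camera in DKO against WT, but not without DKO replicate 3 (adjusted p = 0.081). CD146 selection would be expected to remove most neutrophils. Whether the neutrophils reflect genotype in 1 pool or its isolation stays open.

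Called genes lay close together on chromosomes. Within 20 Mb of Stab2, genes called in Stab2KO were over-represented with the target counted, as planned (Fisher's exact odds ratio 6.96, p = 4.4e-05), with it left out (6.09, p = 0.00028), and with the genes lower in all 3 knockouts also left out (7.31, p = 0.0032), which is consistent with a passenger segment around the targeted locus. For Stab1 the result rests on the target itself: Fisher's exact odds ratio was 4.07 (p = 0.020) with Stab1 counted, as planned, and 3.05 (p = 0.082) without it, so a segment there cannot be told apart from chance. Outside both windows, 8 of the 19 genes called between Stab1KO and Stab2KO had another such gene within 10 Mb (permutation p = 0.036 over 10000 random sets), among them C2, Msh5, H2-Q7 and H2-T23, and passenger segments may be 1 source. Contrasts with DKO were not tested this way, so the falls of Btnl9 and Olfr1396 there are not covered. Altered transcription at the targeted loci, which would also raise Nt5dc2 and Nt5dc3, was not tested.

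The planned check of other liver cell types found a list with a median of at least 0.5 in size in each comparison against WT. The farthest were the stellate list in Stab1KO (-1.39), the Kupffer list in Stab2KO (-1.12) and the neutrophil list in DKO (2.81), at camera adjusted p-values of 5.1e-58, 8.5e-11 and 3.8e-08. With an estimated correlation the adjusted p-values were 0.0033, 0.64 and 0.39. The neutrophil median was 1.05 without DKO replicate 3, and the Kupffer mean went from -1.10 to -0.67 without WT replicate 2. The stellate list was also below -0.5 in Stab2KO (-0.99, adjusted p = 0.032 with an estimated correlation) and DKO (-1.07, adjusted p = 0.13), and passed camera at the preset correlation without each array in turn. Unequal amounts of other cells may contribute to all 3 counts, with the Kupffer and neutrophil lists the weaker grounds for it.

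For the pairwise counts, 3 against 3 arrays make 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real and highest other counts were 74 and 0 for Stab1KO, 71 and 0 for Stab2KO and 432 and 0 for DKO against WT. They were 227 and 0 for DKO against Stab1KO, 822 and 31 for DKO against Stab2KO, and 26 and 1 for Stab1KO against Stab2KO. For the F-test, 1 of 100 splits, the real one with 390 genes, gave as many, and the highest other gave 176. Chance is thus excluded at that level only for the count as a whole. The splits stand for no effect of genotype at all, so they do not show how many of the 390 genes are real. The correlation of the Stab1 effects was 0.10, and 47 of 100 splits gave one as large in size, up to -0.26. That of the Stab2 effects was 0.09, and 48 of 100 gave one as large, up to 0.31, so chance is not excluded for either.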

How the results depend on the processing

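The stellate covariate and the estimated correlation without DKO replicate 3 were chosen after the data were seen. Each array left out in turn moved the counts of called genes to 46 to 81 for Stab1KO, 33 to 92 for Stab2KO and 125 to 510 for DKO against WT, 22 to 357 for DKO against Stab1KO, 45 to 854 for DKO against Stab2KO, 12 to 43 between the single knockouts, 3 to 112 for the departure from additivity and 164 to 434 for the F-test. Fewer arrays also lower the power of the fit. Called lists ranged from 7 to 17, 7 to 15 and 17 to 24 in Stab1KO, Stab2KO and DKO. The effect correlations ranged from 0.00995 to 0.155 for Stab1 and from -0.00704, without Stab2KO replicate 3, to 0.148 for Stab2. The fold changes of Stab1 and Stab2 kept their calls throughout.

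Array weights gave 148, 1111, 466, 1789, 41, 199 and 1020 genes for Stab2KO and DKO against WT, DKO against Stab1KO, DKO against Stab2KO, Stab1KO against Stab2KO, the departure and the F-test; the cause was not tested. A minimum log2 fold change of 1 left 42, 151, 86, 143 and 17 in the first 5 of these, by construction. The 6 compared arrays alone gave 29, 97, 18, 4 and 15, with fewer arrays to estimate the spread. For the departure, the low-signal filter gave 28 and trend with robust options 35; the cause was not tested. The replicate block gave 6 there and moved no other count by over 1.5 times. Olfr1396, Sod3 and Agtr1a (adjusted p = 0.058 each), Sult1a1 (0.067) and Nnt (0.077) lost the departure call with it. Against WT it ended the calls of Adamts13 (0.097), Col6a1 (0.079) and St6gal1 (0.12) in Stab1KO, of Col6a1 (0.086), Pdlim3 (0.082), Reln (0.075), Sncg and Tdg-ps2 (0.051 each) in Stab2KO and of Arntl (0.075), Cmpk2 (0.055), Dnajb9 (0.051) and Hyal2 (0.056) in DKO, and that of Tdg-ps2 (0.078) between the single knockouts. The arrays were not taken as paired, since 4 of 18 same-number pairs, not all, had a correlation of deviations over 0.1. As a hint from the data, 8 of 12 arrays correlated best with their own number, and the mean was 0.075 within numbers against -0.037 between them. Median centring changed no call of a named gene, since the arrays were already quantile normalized.

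With the stellate list mean as a covariate, 1, 0 and 2 genes were called in Stab1KO, Stab2KO and DKO against WT. The covariate separates WT from the knockouts, and the median SE rose from 0.12 to 0.48, 0.35 and 0.45. Over the called genes the median size of the fold change went from 1.40 to 0.58 in Stab1KO, from 1.32 to 0.70 in Stab2KO and from 0.78 to 0.76 in DKO, while the errors grew. The 36 shared falls kept 0.42, 0.48 and 0.50 of their fold in the median, and the other calls 0.45, 0.85 and 1.08. The estimated correlation left 3, 1 and 0 called lists, and 1, 0 and 0 without DKO replicate 3. Without genes near the targets the Stab1 effect correlation was 0.0639, and over genes called in the F-test the correlations were 0.375 and 0.322, by the choice of genes. The mean of the natural killer list in Stab1KO, which was not called, passed at 0.32 without WT replicate 3 and at -0.27 without Stab1KO replicate 3. That of the immediate early list in Stab2KO, not called either, passed at -0.16 without Stab2KO replicate 3 and was 0.19 without Stab2KO replicate 2, so both follow single arrays. Of 156 named gene calls, 59 held and 0 turned under the block, trend with robust options, array weights, median centring, the 6 compared arrays and each array left out; the low-signal filter, every row tested and the minimum fold change were counted but not followed gene by gene. Signal over background was not measured, which limits genes at the low end.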

Other observations

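None of the tests of this part was chosen after the results were seen. Other groups moved in DKO against WT. The cholesterol synthesis list was higher with Fdft1 called (0.95 ± 0.14, SE), at a median of 0.36 (camera adjusted p = 0.00011, and adjusted p = 0.40 with an estimated correlation). Its mean of 0.37 was 0.22 without DKO replicate 3. The YAP target list was higher with Ankrd1, Ajuba (0.83 ± 0.15) and Wwc1 (0.87 ± 0.17) called of 13 (adjusted p = 0.028, and 0.48 with an estimated correlation). The list did not pass without DKO replicate 1 or 2 (adjusted p = 0.17 and 0.089), and Ankrd1, Ajuba and Wwc1 lost the call without 1, 4 and 5 of the arrays in turn. The glucose transporter gene Slc2a1 rose by 1.80 ± 0.36 and the clock gene Arntl by 1.41 ± 0.31. Prox1 and Mmrn1, genes of lymphatic endothelium, rose by 1.06 ± 0.22 and 1.90 ± 0.37 while Reln of the same list fell. Slc2a1 and Arntl each lost the call with any 1 of 9 arrays left out, and Prox1 and Mmrn1 with any 1 of 8 left out.

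Nnt, a gene in which the C57BL/6J substrain carries a deletion, measured 7.95 in WT, 9.08 in Stab1KO, 8.84 in Stab2KO and 8.50 in DKO. The labels do not say whether WT and knockout mice were littermates, and a difference of substrain was not tested, so neither the rise of Nnt in Stab1KO nor its departure is assigned to genotype here. Among the 958 rows unnamed here, 5, 3 and 13 were called in Stab1KO, Stab2KO and DKO against WT.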
